A study of Cunninghamia lanceolata with 3 samples.

How the data were processed

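The series holds 3 RNA-seq libraries from the vascular cambium of Cunninghamia lanceolata (Chinese fir), 1 each from the dormant, the reactivating and the active stage. Per the labels' protocols, the trees were about 16 years old, 15 m tall and 12 cm in diameter and grew under natural conditions, and the cambium was taken as tangential cryosections. Messenger RNA was enriched with oligo(dT) beads, broken into fragments of about 200 bp, copied with random hexamers, amplified by PCR and sequenced on an Illumina HiSeq 2000, per the labels' protocols. The labels do not say how many trees went into each library, and no strand-specific step is described. The groups come from the stage given for each sample.

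Each deposited table lists the unigenes (assembled transcript sequences) with at least 1 read in that library, with the count of uniquely mapped reads, the RPKM (uniquely mapped reads scaled by the length of the unigene in kilobases and by the library total), the percent of the unigene's length covered by reads (coverage) and the length, per the file headers. The count is whole and not normalised. The deposited RPKM equalled the read count divided by the length and by the total named in the header, to a relative tolerance of 1e-06, in every row. Each row also carries the best hit in the NCBI protein collection and gene ontology terms, per the file headers. The assembler, the mapper, their settings and the handling of reads that fit several unigenes are not given in the sources used here. The unigene identifiers end in a suffix naming seedling RNA, which is left out of the names below, and the sources used here do not say what RNA the unigenes were assembled from. No genome was used here, so no positions are given.

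A unigene missing from a table was taken as 0 reads there. Over the 3 libraries 53590 unigenes had a read, and their lengths ran from 150 to 5895 bases with a median of 323. A best hit was given for 30974 (57.8%), and 6117 (11.4%) had a description that names a protein, leaving out unknown, hypothetical, predicted, unnamed and uncharacterised ones. Several unigenes can be fragments of 1 transcript or close copies of a gene family, and reads shared by close copies are outside a unique count. Gene names are those of the best hit in another species, so they name a likely relative and not a tested function.

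With 1 library per stage there is no replicate spread, so no p-value or standard error of a difference between stages was computed, and every difference describes these libraries, not the stages in general. Ratios were taken between the deposited RPKM values. A 95% exact interval of the ratio came from the reads (Clopper-Pearson interval of 1 library's share of the reads in both), and it covers counting error only, because PCR copies are not independent molecules and tree-to-tree variation is not in it. A library at 0 reads was set to a floor of 3 reads and the fold is then a lower bound. The total of 5.84 to 5.85 M reads per library (M for mega) puts 3 reads on a unigene of 1 kilobase at an RPKM of about 0.513. Unigenes entered a comparison with at least 20 reads in both libraries together, and were counted as higher or lower at a ratio of at least 2-fold. For the pattern over the 3 stages, unigenes with at least 50 reads in all were set apart in a library when at least 2-fold above both others or at least 2-fold below both others.

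Before the data were examined, 28 gene lists were fixed as patterns matched to the descriptions, together with the thresholds, the alternatives and the rule for named unigenes. For each list with at least 5 measured unigenes, the median log2 ratio was placed among 10000 random lists of the same size matched in 20 bins of mean expression, and a list is said to stand apart below percentile 2.5 or above percentile 97.5. This percentile describes these libraries and is not a p-value. For the gene sets added in the closing section, 95% bootstrap intervals of the median (2000 resamples of the members) give the spread over members, which are not independent replicates. The random lists were drawn from unigenes with a description that names a protein, a choice made after the data were seen. The named unigenes are, per comparison, the 10 with the largest increase and the 10 with the largest decrease among those with a description that names a protein and at least 200 reads in both libraries together (1 per description). They further include, per list, the 2 most abundant members and the members with the largest ratio each way (at least 100 reads), and the 5 annotated unigenes with the highest RPKM per library. The text gives a part of these, and 1 of them is withheld and not reported here.

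Alternatives were edgeR TMM factors and DESeq2 median-of-ratios size factors as scaling only, no minimum and a minimum of 100 reads, a 4-fold ratio, an interval wholly beyond 2-fold, 1 read added to both libraries, unigenes of at least 500 bases, and reads summed over unigenes with the same description. For the stage pattern a minimum of 200 reads was also used. After the data were seen, 2 more were added, namely all unigenes as the background of the random lists, and totals without the 10 most abundant unigenes of each library. The 3 comparisons share libraries, so the ratios of 1 comparison are not independent of those of another, and no correlation between them was computed. The steps were tested on simulated data, in libraries with the real means and totals where 200 unigenes were changed by known folds. For reactivating against dormant, a simulated 4-fold change was seen as at least 2-fold in 100% of changed unigenes, a 2-fold change in 52% and a 1.5-fold change in 4%. In the run with 4-fold changes, 1.75% of the unchanged ones passed 2-fold from counting error alone among 36268 unigenes. The changed unigenes were drawn from those with more reads than the minimum of the comparisons, so recovery at the lowest counts was not tested. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.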

Results

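The vascular cambium is the sheet of dividing cells that forms wood on its inner side and bark on its outer side. The series measured messenger RNA in this tissue of C. lanceolata, a conifer, at 3 stages of the yearly cycle, with 1 library for each of the dormant, reactivating and active stages. The libraries held 5.85 M uniquely mapped reads in the dormant, 5.85 M in the reactivating and 5.84 M in the active stage, on 49675, 50059 and 50498 unigenes. Because each stage has 1 library, no difference has a replicate check, and the 95% counting intervals given in parentheses after a ratio cover the sampling of reads only.

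The reactivating and active libraries were closest to each other. Across 53590 unigenes, which are not independent replicates, Spearman's rho of the reads was 0.945 between these 2 libraries, 0.869 between reactivating and dormant and 0.868 between active and dormant. In the dormant library the most abundant unigene alone took 2.14% of the reads, against 0.902% for the top unigene of the reactivating library and 0.790% for that of the active library. That dormant unigene, Unigene37845, has a best hit of unknown function and 125423, 638 and 143 reads in the dormant, reactivating and active libraries. Unigene41453, without a hit, had 54668, 317 and 71 reads and was named after its values were seen.

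The first comparison asks what differs between the resting cambium and the cambium that resumes growth. In the reactivating library, many unigenes of the lists for DNA replication, cell division, the cytoskeleton and the loosening and remodelling of growing walls were higher than in the dormant library, some of them absent or nearly so in the dormant library. Most unigenes for dehydrins, late embryogenesis abundant (LEA) proteins and other cold-linked proteins were lower, as were many for starch and sugar metabolism. A part of the cellulose and laccase unigenes was also lower, down to a few reads. Of 36274 unigenes with at least 20 reads in both libraries together, 6136 were at least 2-fold higher in the reactivating library and 5014 were at least 2-fold lower.

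Of the 29 measured unigenes for DNA replication and core histones, 22 were at least 2-fold higher and 0 lower, with a median log2 ratio of 2.37. The large subunit of ribonucleotide reductase (Unigene58072), the enzyme that makes deoxyribonucleotides, had 32 reads in the dormant and 1832 in the reactivating library, 57.2-fold higher (40.4 to 83.9). A small chain of the same enzyme (Unigene54086) had 0 and 247 reads and was at least 82.3-fold higher. A minichromosome maintenance protein (Unigene17730), part of the helicase that opens DNA for copying, was 66.2-fold higher (33.4 to 154). Among 28 cell cycle regulators 17 were higher and 0 lower (median 1.77), including a mitotic cyclin A1-like protein (Unigene56058) with 3 and 170 reads, 56.7-fold higher (19.1 to 277). The spindle checkpoint protein MAD2 (Unigene9577) had 0 and 134 reads and was at least 44.7-fold higher. In contrast, the abundant cell division cycle protein 48 homolog (Unigene52411) was 1.43-fold lower (1.32 to 1.54). Of 21 tubulins and actins, a list that also took in tubulin-folding chaperones, 13 were higher and 0 lower (median 1.53), with an actin (Unigene40842) 106-fold higher (41.0 to 390) and an alpha-tubulin (Unigene6470) 4.16-fold higher (3.75 to 4.62). All 3 lists stood above the matched random lists.

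Wall-modifying enzymes were among the largest increases. Of 28 expansins, xyloglucan endotransglucosylases and endoglucanases, 12 were higher and 3 lower (median 0.66), and of 24 unigenes for pectin modification 13 were higher and 2 lower (median 1.36). Both medians stood above the random lists. An endo-beta-1,4-glucanase (Unigene49670) had 8 reads in the dormant and 2181 in the reactivating library, 273-fold higher (138 to 632), and pectate lyase (Unigene52045) was 73.4-fold higher (42.7 to 138). Expansin 2 (Unigene25630), a protein that loosens walls, was 15.1-fold higher (11.1 to 21.0), while an expansin-like protein (Unigene53531) went the other way, with 611 and 2 reads, 306-fold lower (84.2 to 2529). A beta-1,3-glucanase (Unigene57007) had 1 and 1434 reads, a ratio of 1434 (257 to 56670). It led the defence list by its name, in which 16 of 35 unigenes were higher and 12 lower (median 0.70, above the random lists), while the summed reads of the list were lower, at 13318 in the dormant and 4701 in the reactivating library. In the same list a thaumatin-like protein (Unigene44483) was 62.3-fold lower (49.6 to 79.3), from 4670 to 75 reads.

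The cellulose synthesis list split in 2 directions. Of 43 unigenes 15 were higher and 18 lower, so its median of 0.53, above the random lists, does not describe its members, whose lower quartile was -3.63. A cellulose synthase-like C unigene (Unigene2825) was 5.59-fold higher (3.69 to 8.76). The list took it in by its name, so it need not act in cellulose synthesis. A cellulose synthase catalytic subunit (Unigene45145) had 124 and 3 reads and was 41.3-fold lower (13.8 to 203). In the lignin list, 11 of 67 unigenes were higher and 23 lower, and its median of 0.06 did not stand apart. A laccase (Unigene56615), of the enzyme family that polymerises lignin, was 94.0-fold lower (61.3 to 152), from 1974 to 21 reads, and another laccase (Unigene28704) had 1 and 122 reads, a ratio of 122 (21.5 to 4857). NAC and MYB transcription factors stood below the random lists, with 7 of 27 higher and 12 lower (median -0.79). A myb-related factor (Unigene17426) was 46.6-fold lower (23.4 to 109). The water channel unigene plasma membrane intrinsic protein (Unigene49827) had 2167 and 12 reads and was 181-fold lower (103 to 350). The largest decrease by the rule was an alpha-L-arabinofuranosidase/beta-D-xylosidase (Unigene45159), with 996 reads in the dormant library and 1 in the reactivating library, a ratio of 996 (178 to 39390).

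Cold- and dehydration-linked unigenes were lower as a group. Of 15 dehydrins, LEA and cold-responsive proteins, 11 were lower and 3 higher (median -2.93, below the random lists). An LEA-like protein (Unigene38057) had 5974 and 16 reads, 373-fold lower (230 to 654), and the most abundant dehydrin (Unigene48155) had 7234 and 339, 21.3-fold lower (19.1 to 23.9). A putative abscisic acid-responsive LEA-like protein (Unigene4398) was 14.3-fold higher (8.74 to 24.9). Of 65 unigenes for starch and sugar metabolism 21 were lower and 7 higher (median -0.67, below the random lists), with galactinol synthase 1 (Unigene36635), which starts the synthesis of raffinose sugars, 12.6-fold lower (7.99 to 21.0). A sucrose synthase (Unigene33279) in the same list was 2.20-fold higher (1.88 to 2.59).

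The medians of the hormone lists did not stand apart in this comparison. Auxin transport and response had 18 of 70 unigenes higher and 12 lower (median 0.27), gibberellin 5 of 14 higher and 0 lower (0.59), cytokinin 5 of 24 higher and 6 lower (-0.04), abscisic acid 0 of 17 higher and 4 lower (-0.16) and ethylene 2 of 22 higher and 7 lower (-0.27). The summed reads in the dormant and reactivating libraries were 943 and 3771 for the gibberellin list and 15104 and 19892 for the auxin list. Those of the cytokinin, abscisic acid and ethylene lists were lower in the reactivating library. Single members were far apart. Auxin-induced protein 5NG4 (Unigene54524) had 1 and 729 reads, a ratio of 729 (130 to 28830). A histidine kinase cytokinin receptor (Unigene16439) was 4.61-fold higher (3.64 to 5.90), whereas circadian response regulator 2b (Unigene59341), which the same list took in by its name, was 13.2-fold lower (10.5 to 16.7). The GASA5-like protein (Unigene46844), of a gibberellin-regulated family, was 22.0-fold higher (17.9 to 27.3). A putative WUS homeobox protein (Unigene51479), of the family that keeps stem cells in meristems, was 18.8-fold higher (10.8 to 35.8), although its list of meristem and vascular patterning regulators had 13 of 58 higher and 11 lower (median -0.26) and did not stand apart.

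Terpenoid and resin synthesis, a marker list for resin ducts and bark, stood above the random lists with 5 of 21 higher and 3 lower (median 0.65). The marker lists for differentiating xylem and photosynthesis did not stand apart. Differentiating xylem had 3 of 6 higher and 0 lower (0.90), and photosynthesis, whose measured members were mostly plastid-encoded, had 0 of 12 higher and 4 lower (-0.39). Phloem had 3 measured unigenes, all sucrose transporters, too few to place, of which 2 were lower (median -3.21). Heat shock proteins had 15 of 63 higher and 6 lower (0.29), cytosolic ribosomal proteins 1 of 14 higher and 0 lower (0.43), dormancy and flowering-time regulators 5 of 28 higher and 1 lower (0.18), chromatin modifiers 3 of 35 higher and 4 lower (-0.11) and reactive oxygen scavenging 4 of 21 higher and 6 lower (0.21). Hemicellulose synthesis (4 unigenes, median 0.16) and arabinogalactan proteins (2 unigenes, median 1.83) were too few to place. With unigenes of at least 500 bases alone, the tubulin and actin (0.81, percentile 95.2), cellulose (0.27, percentile 82.7) and wall loosening (0.11, percentile 64.7) medians no longer stood apart, the terpenoid median was -0.28, and the dehydrin list had too few members to place. With a minimum of 100 reads the defence (0.16, percentile 68.6) and terpenoid (0.51, percentile 88.5) medians, and with reads summed by description the cellulose (0.34, percentile 86.8), wall loosening (0.53, percentile 95.9), terpenoid (0.47, percentile 91.3) and NAC and MYB (-0.35, percentile 7.42) medians no longer stood apart.

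**Figure D1:**
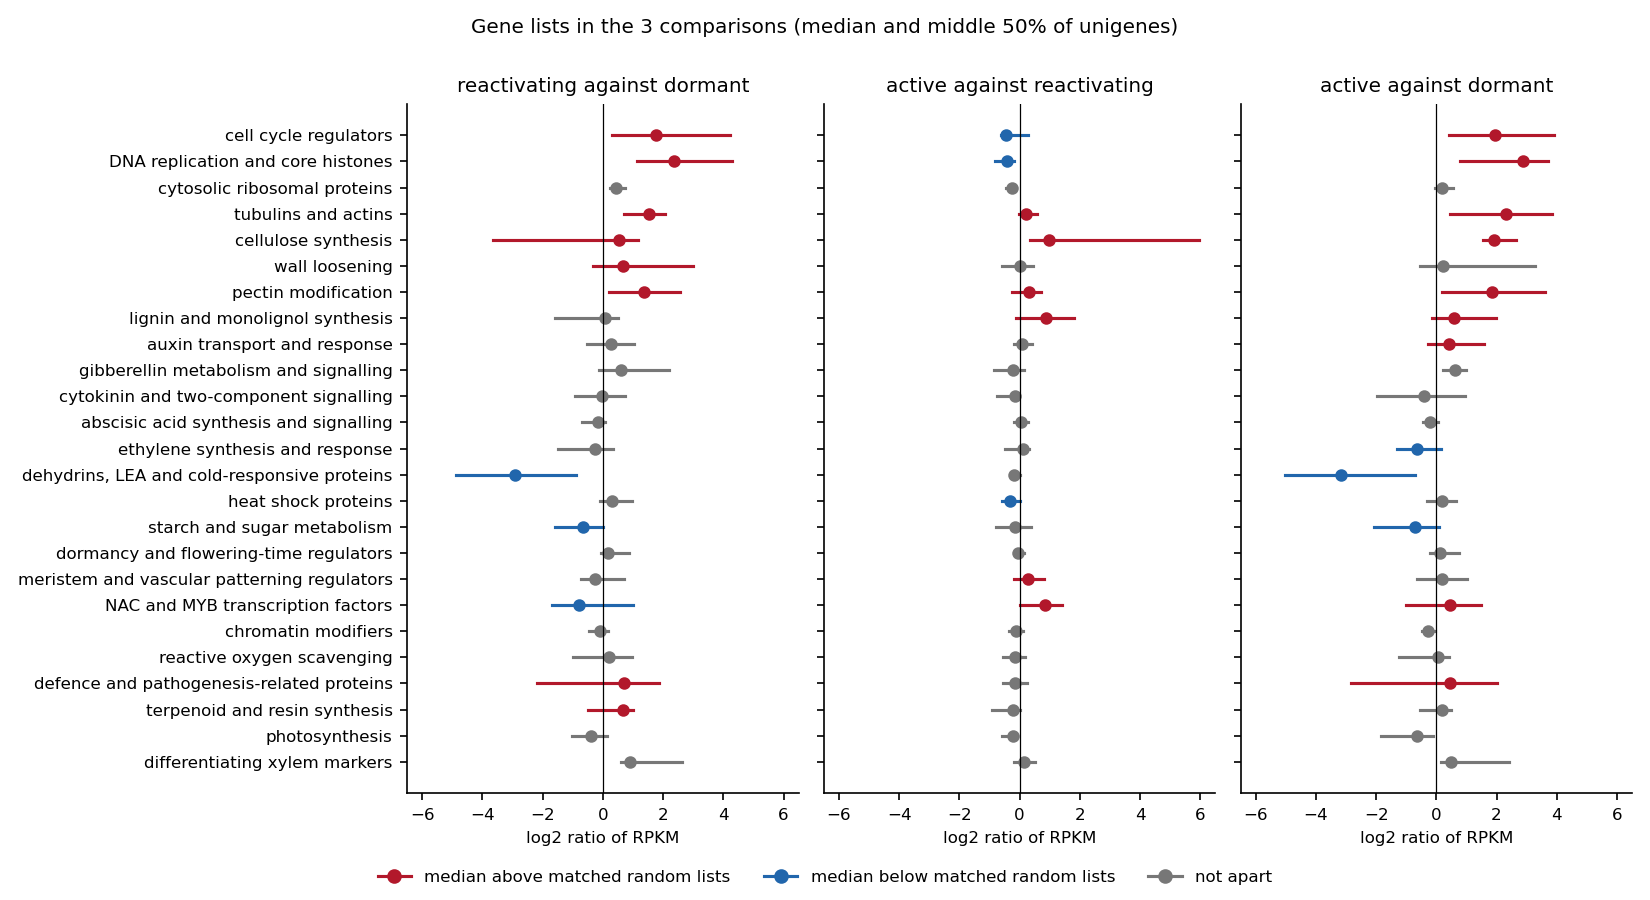
Median log2 ratio of RPKM (points) and middle 50% of the measured unigenes (lines) for the 25 gene lists with at least 5 measured unigenes, in each of the 3 comparisons, with red and blue for medians that stood above or below the matched random lists. DNA replication and core histones sit at 2.37 in reactivating against dormant and at -0.43 in active against reactivating, and the dehydrin list sits at -2.93 and -0.20.

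The second comparison asks what differs between the reactivating and the fully active cambium. Many unigenes for cellulose and lignin synthesis, with laccases and cellulose synthases at the head, and a part of the NAC and MYB transcription factors were higher in the active library, while most of the others in these lists stayed within 2-fold. The medians of the DNA replication and cell cycle lists were slightly lower, with nearly all members within 2-fold, and the summed reads of the cell cycle list were 6582 in the reactivating and 6702 in the active library. Of 36079 measured unigenes, 2439 were at least 2-fold higher in the active library and 1853 at least 2-fold lower, fewer than between either of these libraries and the dormant one.

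In the cellulose list 23 of 47 unigenes were higher and 3 lower (median 0.96). The same catalytic subunit (Unigene45145) had 3 reads in the reactivating and 1141 in the active library, 381-fold higher (130 to 1849), and cellulose synthase Unigene43616 was 97.4-fold higher (61.5 to 165), while cellulose synthase Unigene16267 was 2.13-fold lower (1.43 to 3.22). Of 69 lignin unigenes 29 were higher and 6 lower (median 0.86). The laccase Unigene56615 was 255-fold higher (167 to 413), Laccase-16 (Unigene48367) was 116-fold higher (56.0 to 289) and an abundant phenylalanine ammonia-lyase (Unigene32836), the entry enzyme of phenylpropanoid synthesis, was 2.53-fold higher (2.21 to 2.90), while a 4-coumarate:CoA ligase (Unigene33851) was 2.43-fold lower (2.01 to 2.95). Pinoresinol-lariciresinol reductase (Unigene25524), an enzyme of lignan synthesis, had 0 and 422 reads and was at least 141-fold higher. The plasma membrane intrinsic protein (Unigene49827) was 178-fold higher (102 to 346). Of 26 NAC and MYB factors 12 were higher and 0 lower (median 0.85), and R2R3-Myb4 (Unigene1847) had 1 and 129 reads, a ratio of 129 (22.8 to 5140). These 3 lists stood above the random lists.

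The lists of tubulins and actins (3 of 21 higher and 1 lower, median 0.21), pectin modification (4 of 27 higher and 2 lower, median 0.30) and meristem and vascular patterning (6 of 58 higher and 1 lower, median 0.27) also stood above the random lists, with most members within 2-fold. Tubulin beta-6 (Unigene39485) was 4.75-fold higher (4.17 to 5.43), and a clavata-like receptor (Unigene45241) was 2.59-fold higher (1.82 to 3.76). Cell cycle regulators (1 of 30 higher and 1 lower, median -0.45), DNA replication and core histones (0 of 30 higher and 2 lower, -0.43) and heat shock proteins (2 of 61 higher and 6 lower, -0.32) stood below. The minichromosome maintenance protein (Unigene17730) was 1.79-fold lower (1.55 to 2.07) and thymidylate synthase (Unigene38338), which makes a DNA building block, was 1.79-fold lower (1.5 to 2.15).

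The largest decreases by the rule were in other classes. A putative phosphate transporter (Unigene57796) had 345 reads in the reactivating and 30 in the active library, 11.5-fold lower (7.90 to 17.3), and an SPX domain-containing protein (Unigene53067), of a family that takes part in phosphate sensing, was 5.02-fold lower (4.22 to 6). A vacuolar iron transporter-like protein (Unigene16089) was 8.03-fold lower (5.24 to 12.8), and alpha pinene synthase (Unigene10582), which makes a resin monoterpene, was 5.74-fold lower (4.88 to 6.77). Unigenes with names of mitochondrial genes were in the same group, namely orf173 (Unigene8735) at 4.08-fold lower (3.43 to 4.89), NADH dehydrogenase subunit 2 (Unigene53825) at 3.96-fold lower (2.95 to 5.39) and subunit 7 (Unigene58661) at 3.51-fold lower (2.65 to 4.71).

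The other lists did not stand apart between the active and reactivating libraries in the main analysis. With reads summed by description, 5 lists stood below the random lists, against 3 in the main analysis, so not all of these lists kept this verdict. Wall loosening had 2 of 29 unigenes higher and 3 lower (median 0.02), auxin 12 of 74 higher and 1 lower (0.09), gibberellin 1 of 15 higher and 3 lower (-0.22), cytokinin 2 of 23 higher and 4 lower (-0.15), abscisic acid 0 of 17 higher and 1 lower (0.03), ethylene 2 of 21 higher and 0 lower (0.12) and dehydrins, LEA and cold-responsive proteins 0 of 12 higher and 0 lower (-0.20). Starch and sugar metabolism had 7 of 61 higher and 10 lower (-0.16), with a cell wall beta-fructofuranosidase (Unigene54463) 7.21-fold lower (4.10 to 13.7) and a sucrose synthase (Unigene37816) 3.87-fold higher (3.10 to 4.88). Cytosolic ribosomal proteins had 0 of 14 higher and 0 lower (-0.24), dormancy and flowering-time regulators 2 of 29 higher and 1 lower (-0.05), chromatin modifiers 2 of 35 higher and 1 lower (-0.13), reactive oxygen scavenging 0 of 22 higher and 2 lower (-0.14) and defence proteins 5 of 35 higher and 3 lower (-0.16). Among the marker lists, terpenoid and resin synthesis had 2 of 21 higher and 5 lower (-0.23), photosynthesis 1 of 9 higher and 1 lower (-0.22) and differentiating xylem 0 of 6 higher and 0 lower (0.14). Hemicellulose synthesis (4 unigenes, median 0.26), arabinogalactan proteins (2 unigenes, 0.05) and phloem (3 unigenes, 0.25) were too few to place. The median of tubulins and actins was -0.09 with unigenes of at least 500 bases, that of meristem regulators was -0.03 with reads summed by description and 0.07 (percentile 86.7) with unigenes of at least 500 bases, and those of pectin modification (0.18, percentile 91.6) and of tubulins and actins (0.13, percentile 87.3) no longer stood apart with reads summed by description. Counting intervals wholly beyond 2-fold left 961 unigenes higher and 311 lower.

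**Figure D2:**
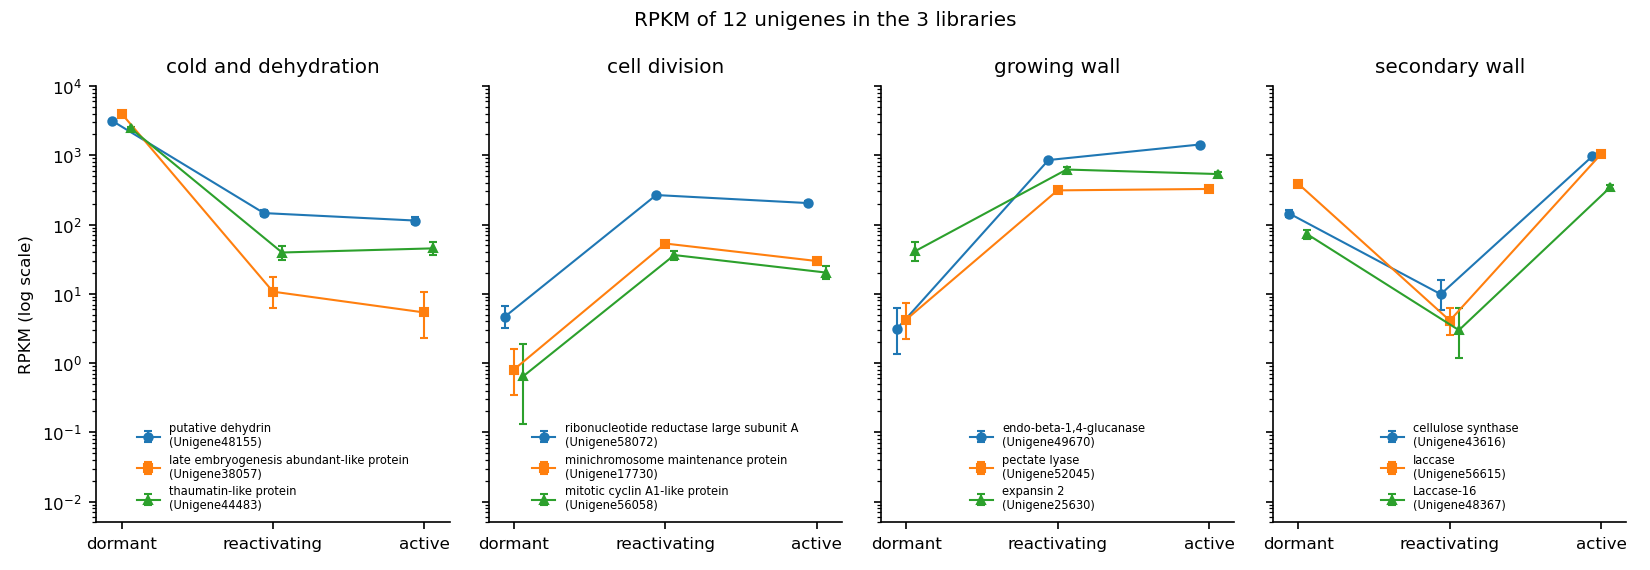
RPKM on a log scale of 12 named unigenes in the dormant, reactivating and active libraries, in 4 groups of 3, with bars for 95% exact Poisson intervals of the reads. The dehydrin, LEA-like and thaumatin-like unigenes are highest in the dormant library, the division and growing-wall unigenes are lowest there, and the cellulose synthase and 2 laccases are lowest in the reactivating library, with the laccase Unigene56615 at an RPKM of 386, 4.10 and 1048. The thaumatin-like unigene, drawn under cold and dehydration, is of the defence list. The 12 were picked and do not stand for their lists, in which the expansin-like Unigene53531 and the laccase Unigene28704 went the other way.

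The third comparison sets the active against the dormant library, the ends of the series. Many division, cytoskeleton and pectin unigenes were higher in the active library, as were cellulose unigenes nearly throughout their list. Many dehydrin, LEA and cold-responsive unigenes and a part of sugar metabolism were lower. Of 36288 measured unigenes, 6560 were at least 2-fold higher in the active library and 5005 at least 2-fold lower.

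Cellulose synthesis had 41 of 44 unigenes higher and 2 lower (median 1.92), with a catalytic subunit (Unigene59204) 13.0-fold higher (10.8 to 15.8) and cellulose synthase Unigene16267 6.84-fold lower (4.85 to 9.88). DNA replication and core histones had 18 of 27 higher and 0 lower (2.88), cell cycle regulators 16 of 27 higher and 0 lower (1.97), tubulins and actins 13 of 21 higher and 0 lower (2.32) and pectin modification 17 of 27 higher and 3 lower (1.85). Lignin synthesis had 27 of 72 higher and 14 lower (0.59), where laccase Unigene4888 had 2 and 857 reads, a ratio of 429 (118 to 3547), and a dirigent-like protein (Unigene6520) had 142 and 2 reads, 70.9-fold lower (19.3 to 591). Auxin transport and response had 24 of 74 higher and 6 lower (0.42), NAC and MYB factors 14 of 32 higher and 8 lower (0.46) and defence proteins 12 of 36 higher and 13 lower (0.45). All 9 medians stood above the random lists, although the summed reads of the defence list were lower, at 13318 in the dormant and 4470 in the active library. A kinesin heavy chain (Unigene14442), a motor on microtubules, was 4.97-fold higher (4.47 to 5.54), a putative regulator of cytokinesis (Unigene57967) was 40.9-fold higher (18.5 to 112) and a class III homeodomain leucine zipper protein (Unigene49245), of a family that patterns vascular tissue, was 16.4-fold higher (8.08 to 38.8).

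Dehydrins, LEA and cold-responsive proteins had 3 of 15 higher and 9 lower (median -3.18), starch and sugar metabolism 6 of 65 higher and 28 lower (-0.70) and ethylene 1 of 22 higher and 9 lower (-0.64), and all 3 stood below the random lists. The summed reads of the ethylene list were close, however, at 3714 in the dormant and 3608 in the active library. A dehydrin (Unigene20916) had 2036 reads in the dormant library and 1 in the active library, a ratio of 2034 (365 to 80380), and the low-temperature-induced-like protein (Unigene14523) was 42.2-fold lower (35.6 to 50.3). A beta-fructofuranosidase (Unigene17421), which splits sucrose, was 59.1-fold lower (30.9 to 130), and a sucrose-phosphate synthase (Unigene32854) was 8.18-fold lower (6.87 to 9.82). In the ethylene list, ACC oxidase unigenes, for the last step of ethylene synthesis, went both ways, with Unigene12937 91.8-fold higher (41.9 to 251) and Unigene14066 4.79-fold lower (3.68 to 6.32). A 3-hydroxy-3-methylglutaryl coenzyme A reductase (Unigene13583), of the mevalonate pathway, was 57.1-fold lower (24.2 to 177).

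The other lists did not stand apart in active against dormant. Wall loosening had 13 of 28 higher and 3 lower (median 0.23), gibberellin 4 of 13 higher and 2 lower (0.63), cytokinin 6 of 24 higher and 8 lower (-0.40), abscisic acid 0 of 16 higher and 3 lower (-0.22), heat shock 10 of 63 higher and 7 lower (0.19) and ribosomal proteins 0 of 14 higher and 0 lower (0.20). Dormancy and flowering-time regulators had 5 of 30 higher and 3 lower (0.13), with pseudo-response regulator 7 (Unigene13619) 4.19-fold lower (3.17 to 5.62). Meristem regulators had 15 of 60 higher and 9 lower (0.18), chromatin modifiers 2 of 35 higher and 2 lower (-0.26), reactive oxygen scavenging 1 of 21 higher and 6 lower (0.06), terpenoid synthesis 3 of 21 higher and 3 lower (0.18), photosynthesis 0 of 12 higher and 5 lower (-0.64) and differentiating xylem 3 of 7 higher and 0 lower (0.47). Hemicellulose synthesis (4 unigenes, 0.49), arabinogalactan proteins (2 unigenes, 1.88) and phloem (3 unigenes, -3.09) were too few to place. The defence median was -0.29 with a minimum of 100 reads and 0.42 (percentile 97.4) with 1 read added, the ethylene median -0.09 (percentile 39.0) and the tubulin and actin median 0.23 (percentile 65.4) with unigenes of at least 500 bases, and with reads summed by description the auxin (0.26, percentile 85.0), ethylene (-0.16, percentile 28.3) and defence (0.32, percentile 91.3) medians no longer stood apart. At 500 bases the NAC and MYB median was at percentile 97.2, the defence median was at percentile 92.8 and the dehydrin list had too few members to place, while wall loosening stood above the random lists with a minimum of 100 reads (1.20).

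Over the 3 stages, most unigenes that stood apart in 1 library did so in the dormant one. Of 31946 unigenes with at least 50 reads in all, 2589 were highest and 4128 lowest in the dormant library by at least 2-fold against both others. The active library was highest for 1008 and lowest for 665, and the reactivating library was highest for 437 and lowest for 873. Of these 873, 757 also had counting intervals that excluded a ratio of 1 against both other libraries. A library at 0 reads counted as 3 reads here, so a library with 1 read could be called lowest in its place. R2R3-Myb4 (Unigene1847), with 0, 1 and 129 reads, met the rule for the reactivating library in this way. Cell cycle regulators (14 of 25) and DNA replication and core histones (17 of 26) were mainly lowest in the dormant library, and dehydrins, LEA and cold-responsive proteins (9 of 15) mainly highest there. Of 43 cellulose unigenes 18 were lowest in the reactivating library and 22 highest in the active library, and of 70 lignin unigenes 18 and 17 were, against 154 and 170 of 3899 unigenes whose description names a protein. A unigene can be in both classes. The median log2 ratio in active against dormant was 2.66 for the 18 cellulose unigenes, so many of these are in both, and 0.25 for the 18 lignin unigenes. The 18 cellulose unigenes carry 5 different descriptions and the 18 lignin unigenes 8, so several can be fragments or copies of the same transcript. The 18 cellulose unigenes lowest in the reactivating library summed to 1832, 143 and 11985 reads in the dormant, reactivating and active libraries, and the other 25 to 2055, 3331 and 5101.

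**Figure D3:**
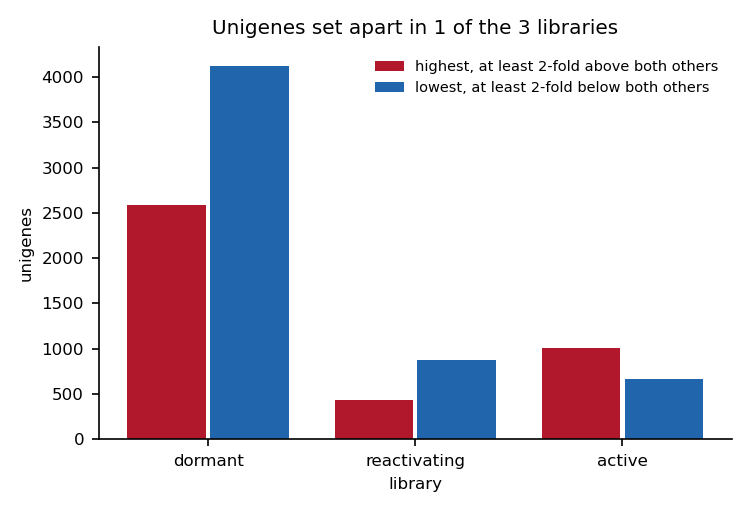
Number of unigenes (y axis) at least 2-fold above both other libraries (red bars) or at least 2-fold below both others (blue bars) in each library, among 31946 unigenes with at least 50 reads. The dormant library has 2589 and 4128, the reactivating library 437 and 873 and the active library 1008 and 665.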

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

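The settings with all unigenes as background and with totals without the 10 most abundant unigenes were chosen after seeing the data. The scaling barely mattered for signs and counts. With edgeR TMM factors and with DESeq2 size factors every list median that stood apart kept its sign, and every count stayed within 1.5 times. With both, 2 medians near 0 that did not stand apart changed sign (lignin in reactivating against dormant and dormancy regulators in active against reactivating). The place against the random lists could not change, because a new scaling shifts all ratios of a comparison, and those of its random lists, by the same amount. No paired analysis was possible because each stage has 1 library. There was also no replicate to leave out, so the tree, the section and the library preparation cannot be separated from the stage. Depth limits low unigenes most, and the counts fall with stricter minimums because fewer unigenes are tested or fewer pass. The 2 settings chosen after seeing the data gave 166 list medians with the same verdict, 2 that newly stood apart and 18 counts within 1.5 times. Over the planned settings 464 list medians had the same verdict, 22 no longer stood apart, 11 newly did and 4 that had stood apart changed sign. The 464 include 84 with edgeR TMM factors and 84 with DESeq2 size factors. The 166 include 84 with totals without the 10 most abundant unigenes. These settings change only the scaling, so their verdicts against the random lists were bound to stay the same. The 464 and the 166 also count lists that stood apart in neither setting and lists with too few members to place. The 464 and the 166 therefore do not measure how often a median that stood apart kept its place. The 22 include the dehydrin list against the dormant library, which had too few long unigenes to place.

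Counts higher and lower in reactivating against dormant were 3129 and 2465 at 100 reads, 3202 and 2254 with intervals beyond 2-fold, 2456 and 1728 at 4-fold and 2328 and 1865 at 500 bases, and 8324 were lower with no minimum. In active against reactivating they were 5539 and 3864 with no minimum, 1004 and 536 at 100 reads, 961 and 311 with intervals beyond 2-fold, 774 and 245 at 4-fold and 901 and 431 at 500 bases. In active against dormant they were 3486 and 2583 at 100 reads, 3666 and 2306 with intervals beyond 2-fold, 2843 and 1637 at 4-fold and 2600 and 1767 at 500 bases, and 10213 were higher with no minimum. Highest and lowest in dormant, reactivating and active were 1360 and 2294, 146 and 374, 528 and 246 at 200 reads, and 824 and 1767, 34 and 335, 316 and 92 at 4-fold. Lists above the random lists numbered 5 in reactivating against dormant at 500 bases and also with reads summed by description (8 in the main analysis), and 3 in active against reactivating with summed reads, where 5 were below. In active against dormant 1 list was below at 500 bases. Medians that had stood apart changed sign in 4 cases, and the cause was not tested. They were terpenoids in reactivating against dormant (-0.28 at 500 bases), tubulins and actins (-0.0941 at 500 bases) and meristem regulators (-0.0335 with summed reads) in active against reactivating, and defence in active against dormant (-0.29 at 100 reads).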

Other observations

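All tests in this part were chosen after the results they measure had been seen. Gene ontology terms were scanned as deposited, which gave 193 terms with 20 to 500 measured unigenes in reactivating against dormant. Of these, 25 stood above the matched random lists and 18 below. By chance 4.8 would fall on each side if the members of a term varied like randomly drawn unigenes. Fragments or copies of the same transcript can break this, and the terms are not independent of each other. The enzyme linked receptor protein signaling pathway had 28 of 53 unigenes higher in the reactivating library and 5 lower (median log2 ratio 1.27), and proteins anchored to membrane 20 of 41 higher and 0 lower (0.94). L-phenylalanine metabolic process had 1 of 38 higher and 15 lower (-0.76), and drug transport 2 of 39 higher and 14 lower (-0.60). DNA metabolic process had 61 of 166 higher and 15 lower (0.49, percentile 100) and chromatin 24 of 51 higher and 2 lower (0.89, percentile 100), while DNA-dependent DNA replication was nearly even, with 8 of 35 higher and 9 lower (-0.25, percentile 6.03). In active against dormant the last term had 8 of 35 higher and 13 lower (-0.52, percentile 0.21), against the direction of the DNA replication list. In active against reactivating, lignin metabolic process had 14 of 21 higher and 1 lower (2.32), arginine metabolic process 0 of 28 higher and 0 lower (-0.50) and cellular response to starvation 3 of 49 higher and 8 lower (-0.32).

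The 873 unigenes lowest in the reactivating library summed to 151606, 19560 and 183481 reads in the dormant, reactivating and active libraries. Read sampling is argued against as the whole source, since 100 draws of Poisson counts, with each unigene at the same rate in the reactivating library and in the lower of the other 2, gave at most 87 such unigenes (PCR copies are not in this model). Fragments of a few transcripts are argued against only for the 154 with a description that names a protein. These carry 113 different descriptions, cellulose synthase catalytic subunit (13) and laccase (8) being the most frequent. Fragments of 1 transcript can carry different descriptions, so this is not a count of transcripts, and the rest of the 873 were not covered. Less xylem in the reactivating section would lower xylem markers, but the fixed list had a median log2 ratio of 0.90 against the dormant library. Xylem serine proteinase unigenes had 33 and 291 (Unigene51035) and 233 and 373 reads (Unigene49674), but a metacaspase (Unigene32338) was lower, at 165 and 129. These values argue against less xylem only as far as 6 unigenes named by best hit and a bound set after the values were seen allow. Whether these 6 follow the amount of xylem that was forming walls was not tested, so less of that tissue stays open. A difference between the stages stays open and untested, as does a difference between trees or sections, which 1 library per stage cannot exclude.

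Transcripts encoded by organelles were lower in the active library. Of 29 measured unigenes with names of mitochondrion-encoded genes, 15 were at least 2-fold lower than in the reactivating library and 0 higher (median log2 ratio -1.05). A carry-over of organelle RNA through the oligo(dT) selection, equal for both organelles, stays open because the comparisons part: against the reactivating library the plastid-encoded median was -0.60 (bootstrap interval over members -0.69 to -0.23) and the mitochondrial interval -1.29 to -0.83, while against the dormant library both medians were -0.93 (-1.06 to -0.69 and -1.20 to -0.54). In reactivating against dormant the mitochondrial median was 0.12 (-0.17 to 0.44) and the plastid-encoded median -0.27 (-0.54 to -0.13), with intervals that overlap. Fewer mitochondria as the whole cause would lower nuclear-encoded mitochondrial proteins about as much, if their transcripts follow the number of mitochondria, and their medians of -0.15 (-0.35 to -0.06) against the reactivating and 0.06 (-0.15 to 0.23) against the dormant library argue against it. A smaller part for fewer mitochondria and a stage difference in organelle transcription stay open and were not tested.

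Unigenes with a best hit outside green plants numbered 29 and took 0.0606% of reads in the dormant (95% exact binomial interval 0.0586 to 0.0626), 0.0843% in the reactivating (0.0820 to 0.0867) and 0.0857% in the active library (0.0834 to 0.0881). Against the dormant library their median log2 ratio was 0.20 in the reactivating (bootstrap interval over members -0.22 to 0.70) and 0.19 in the active library (-0.21 to 0.85). Neither median stood apart from the random lists.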
